A study of Selaginella moellendorffii with 7 samples.

How the data were processed

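RNA abundance was measured by sequencing in 7 libraries of wild-type Selaginella moellendorffii, a spikemoss. The developmental stage given in the labels placed 3 libraries in a class of small sporangia, 3 in a class of big sporangia and 1 in young microphyll, the leaf tissue that served as control. Sporangia were taken from sporophylls, the leaves that bear them. Per the labels' protocols, total RNA was extracted with TRIzol, libraries followed the standard Illumina protocol, and the design text names an Illumina HiSeq instrument as sequencer. The aligner, the genome build, the gene annotation and the counting tool are not given in the sources used here.

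The deposited values are RPKM, reads scaled to the length of the gene and the total of the library, computed by the authors per the file headers, with 1 table per library. Each table lists only genes with a value above 0, so a gene missing from a library was set to 0. Across the 7 libraries 19678 genes were listed, 15569 of them in every library and 740 in 1 library. The genes carry numeric IDs that the files do not pair with names. None could be matched to the reference table of gene names, where 0 of 37888 entries shared an ID, so the IDs are given as deposited and no position, exon or product is stated. For the same reason the 23 gene lists and the 5 protein motif lists that had been fixed before the data were examined could not be filled, and no gene list was tested.

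Depth was recovered from the values. RPKM made from whole reads takes steps whose size depends on the length of the gene and on the total of the library. Relative depth came from genes below 3 RPKM with the same count in both libraries of a pair. The total of the first library was the largest at which nearly all of 1137 genes listed in every library had a whole-number length, and 99.6% of them did. Each gene then received the smallest whole length of at least 60 nt under which all its values were whole reads. With these totals and lengths 100% of the 124645 values came out whole within a tolerance of 0.01 reads. A gene whose counts share a divisor can be placed too low by this step. The totals ran from 5073407 to 5574198 reads, a ratio of 1.10 between the deepest and the shallowest library, and the reads of the listed genes summed to 99.8% of each. The median recovered length was 1041 nt, and 86.7% of lengths were multiples of 3. A gene of that length at 1 RPKM held between 5.28 and 5.80 reads, and the limit that a count of 0 allows (3 reads) lay between 0.517 and 0.568 RPKM. The smallest count listed was 1 read. These limits cover counting error only, since no molecular identifiers mark separate molecules. Simulated tables of 3909 genes gave back all 7 totals and 99.7% of the read counts exactly.

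Values were analysed as log2(RPKM + 1), with a pseudocount of 1 RPKM, so fold changes understate the change of genes with low values. Genes whose mean over the 3 group means reached 1 RPKM were kept, which left 15630. A linear model with 3 groups was fitted to all 7 libraries with limma 3.58.1 in R 4.3.3, with a trend of the prior variance on abundance. It had 4 residual degrees of freedom and 4.79 prior degrees of freedom. The contrasts were big minus small sporangia, and the mean of both sporangium classes minus microphyll. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p of 0.05. The lone microphyll library added no degree of freedom and was assumed to vary like the sporangium libraries. The design fixed before the data were examined assumed RPKM values, and its tests were used as written. The rule for naming genes, also fixed beforehand, asked for the largest fold changes past the threshold with no overlap between the libraries of the compared sides, and limited IDs without names to 2 that rose and 2 that fell in each comparison.

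Means are given with the SD over libraries. Library pairs were compared by Pearson's r of log2(RPKM + 1) across all listed genes and by a chi-square test of their recovered reads. Within a class the chi-square value per degree of freedom ran from 6.31 to 16.1, so no pair agreed within sampling noise. Each library was counted on its own, though these values do not tell separate plants from separate libraries of 1 sample. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

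The tests were checked on simulated data. Negative binomial reads were drawn from the real means and library totals with the same dispersion of 0.0111, a median over abundant genes, for every gene. In each comparison 200 genes above a floor on mean reads were changed by 2-fold or 4-fold. For big against small sporangia, with 15787 genes tested, limma recovered 85.0% of the 2-fold and 99.0% of the 4-fold changes, and 7 of its 191 calls were false. For sporangia against microphyll, with 15730 genes tested, it recovered 56.6% of the 2-fold and 94.9% of the 4-fold changes, and 17 of 167 calls were false. That share of false calls lies above the 0.05 at which the adjusted p was cut. Real genes differ in their spread, and genes with few reads were not changed here. Recovery may therefore be lower, and false calls more frequent, in the real data.

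Alternatives planned before the data were examined were pseudocounts of 0.1 and 5 RPKM, no filter, a filter of 5 RPKM, scaling by a trimmed mean of M values or by the median ratio to the geometric mean, quantile normalization, no variance trend, the number in the sample title, centred within each size class, as a covariate, an added limit of 1 on the absolute log2 fold change, a fit to the 6 sporangium libraries alone, and leaving out each sporangium library in turn. The trimmed mean left out a share of 0.3 of genes at either end of the log ratios and 0.05 at either end of abundance. Alternatives chosen after seeing the data were voom, the weighting in limma for read counts, on the recovered reads, voom together with the trimmed mean scaling, and leaving out big replicate 1 and small replicate 1 together. Summing near-identical gene copies had been planned and was not run, since no gene sequences were used here, so reads shared between such copies remain a source of uncertainty for any gene.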

Results

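Transcript abundance was measured in sporangia and leaves of Selaginella moellendorffii, a spikemoss of the lycophyte lineage, by RNA sequencing of 7 libraries from wild-type plants. Sporangia are the organs in which spores form after meiosis, and in this plant they sit on leaf-like sporophylls. The labels divide the sporangia by size, with 3 libraries from small and 3 from big sporangia, and 1 library of young microphyll, the small leaf of this plant, served as control. The deposited tables give RPKM, and the whole reads behind them could be recovered, with totals of 5410937, 5218768 and 5574198 reads for small replicates 1 to 3, 5179610, 5459061 and 5500778 reads for big replicates 1 to 3, and 5073407 reads for the microphyll. Between 17905 and 18152 genes were listed in each sporangium library and 16735 in the microphyll, and the 10 most abundant genes took between 6.40% and 8.67% of reads. The labels do not say how size was set, which kind of spore the sporangia held, or whether the 3 libraries of a class came from separate plants or from further stages. The p-values therefore measure only the spread between these samples, which may be technical or may hold differences of stage.

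Libraries grouped by organ and by size class. Pearson's r of log2(RPKM + 1), taken across genes, which are not independent replicates, ran from 0.977 to 0.980 among the small sporangia and from 0.975 to 0.983 among the big sporangia. Small and big libraries correlated less, between 0.938 and 0.956. By Pearson's r the microphyll stood farther from the big class, at 0.904 to 0.912, than from the small class, at 0.916 to 0.935, in each of the 3 libraries of either class. By chi-square per degree of freedom of the reads the ranges overlapped, at 51.6 to 68.0 for the big and 36.0 to 52.5 for the small class. A difference between these ranges has no replicate check on the microphyll side.

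**Figure D1:**
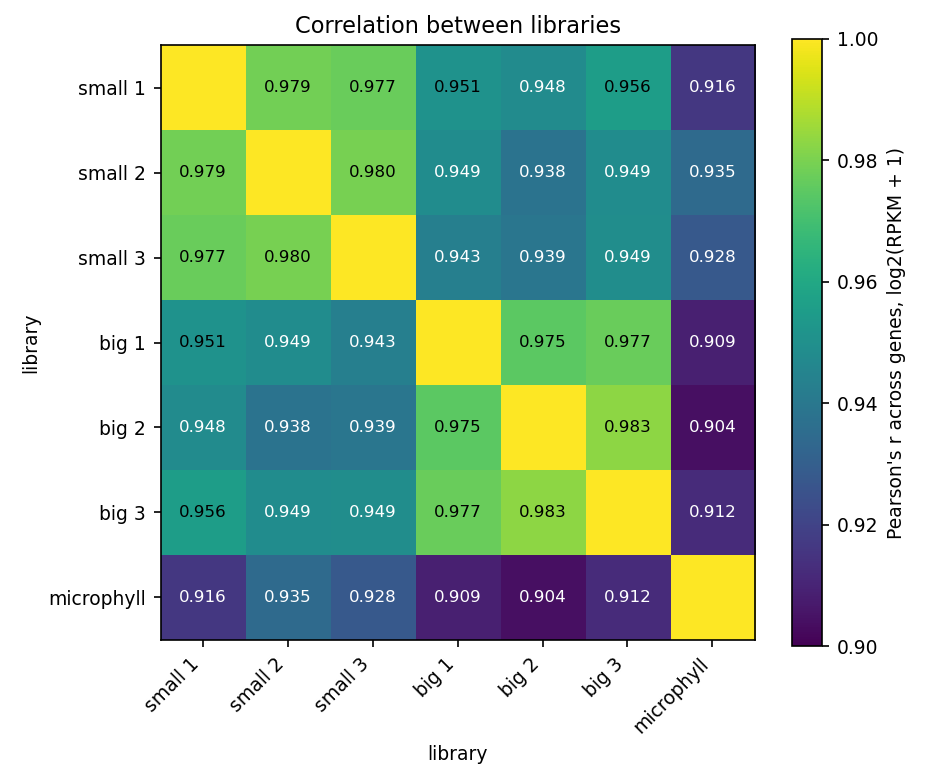
Pearson's r of log2(RPKM + 1) across genes for every pair of the 7 libraries, with small and big sporangia numbered by replicate on both axes and colour giving r. Values within a size class lie at 0.975 or above, and those with the microphyll lie between 0.904 and 0.935.

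The comparison of big with small sporangia asked which transcripts differ between the size classes of a developing sporangium. Of 15630 genes tested, 1162 were higher and 1547 were lower in big sporangia. The 1162 genes higher in big sporangia held 5.16% ± 0.41 of reads in small sporangia and 14.5% ± 2.06 in big sporangia (SD, n = 3 in each class), and 6.14% in the microphyll. A large part of this rise lay in 21 of them, picked for high values in big sporangia and low values in small replicate 3. These held 6.17%, 4.07% and 3.03% of reads in big replicates 1 to 3, and 0.604%, 0.280% and 0.0197% in small replicates 1 to 3. The 1547 genes lower in big sporangia went from 15.3% ± 0.41 of reads in small sporangia to 6.91% ± 0.38 in big sporangia (SD, n = 3 in each class), with 10.02% in the microphyll. Abundant transcripts were on both sides, since 266 of the genes higher in big sporangia averaged at least 100 RPKM there and 316 of the genes lower in big sporangia averaged at least 100 RPKM in small sporangia.

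Most of these changes were moderate and a small part was large. The median log2 fold change was 1.02 among the genes that rose and -1.12 among those that fell, on the log2(RPKM + 1) scale. A change of at least 4-fold was seen in 159 genes that rose and 209 that fell, and a change of at least 16-fold in 27 and 8. The genes that rose had a median length of 1059 nt and those that fell 1128 nt, against 1093 nt for all genes tested. Presence and absence played little part: 75 genes were listed in all 3 small libraries and in no big library, and 66 the other way round, but only 1 gene on either side had 20 or more reads in each library of its class.

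The files do not pair gene IDs with names, so the genes at the extremes are given by ID alone. Gene 159799 averaged 418.7 ± 407 RPKM in small and 7075 ± 2332 RPKM in big sporangia (SD, n = 3 in each class), and it stood at 13.8 RPKM in the microphyll. Its log2 fold change was 5.55 with an SE of 1.39 (limma, adjusted p = 0.0259). The small libraries were far apart for this gene, at 821, 427 and 7.83 RPKM in replicates 1, 2 and 3. Its log2 fold change was 6.79, 6.32 and 3.52 without small replicate 1, 2 and 3, and without big replicate 1, 2 or 3 it was 5.30, 5.56 and 5.78 and no longer passed the threshold with fewer libraries (limma, adjusted p = 0.0736, 0.0683 and 0.0556). At the same log2 fold change of 5.55 it did not pass without the filter on low values (limma, adjusted p = 0.0620) or without the variance trend (limma, adjusted p = 0.0504).

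Gene 419005 averaged 3.26 ± 3.21 RPKM in small and 258 ± 234 RPKM in big sporangia (SD, n = 3 in each class), where its values were 249, 496 and 28.2 RPKM. Its log2 fold change was 5.47 with an SE of 0.95 (limma, adjusted p = 0.00492), and it was 6.05 without small replicate 2, 4.62 without big replicate 2 and 6.66 without big replicate 3. Genes 159799 and 419005 both belong to a group of 21 genes picked for a mean of at least 100 RPKM in big sporangia and under 1/50 of that in small replicate 3. In the other direction, gene 413730 averaged 1043 ± 430 RPKM in small and 31.2 ± 41.3 RPKM in big sporangia (SD, n = 3 in each class), a log2 fold change of -6.02 with an SE of 0.93 (limma, adjusted p = 0.00282), which was -4.90 without big replicate 1 and -7.21 without big replicate 2. Gene 404922 was even across the small class, at 248 ± 18.5 RPKM, and averaged 6.35 ± 8.38 RPKM in the big class (SD, n = 3 in each class). Its log2 fold change was -5.71 with an SE of 0.64 (limma, adjusted p = 0.00066) and -6.63 without big replicate 3, and it had 0 reads in the microphyll, which at its length and that depth allows up to 3 reads.

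The counts rest on limma with an adjusted p below 0.05, which 2709 genes (17.3%) passed, and 4801 genes had an unadjusted p below that value. The libraries of the size classes did not overlap for 2703 of the 2709 genes and for 35.4% of all genes tested, where chance gives 10%. With an added limit of 2-fold the count was 1482 genes, 600 higher and 882 lower. Without big replicate 2 it was 1752 genes with 680 higher, and the number higher was 737 without big replicate 3 and 770 without small replicate 2.

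**Figure D2:**
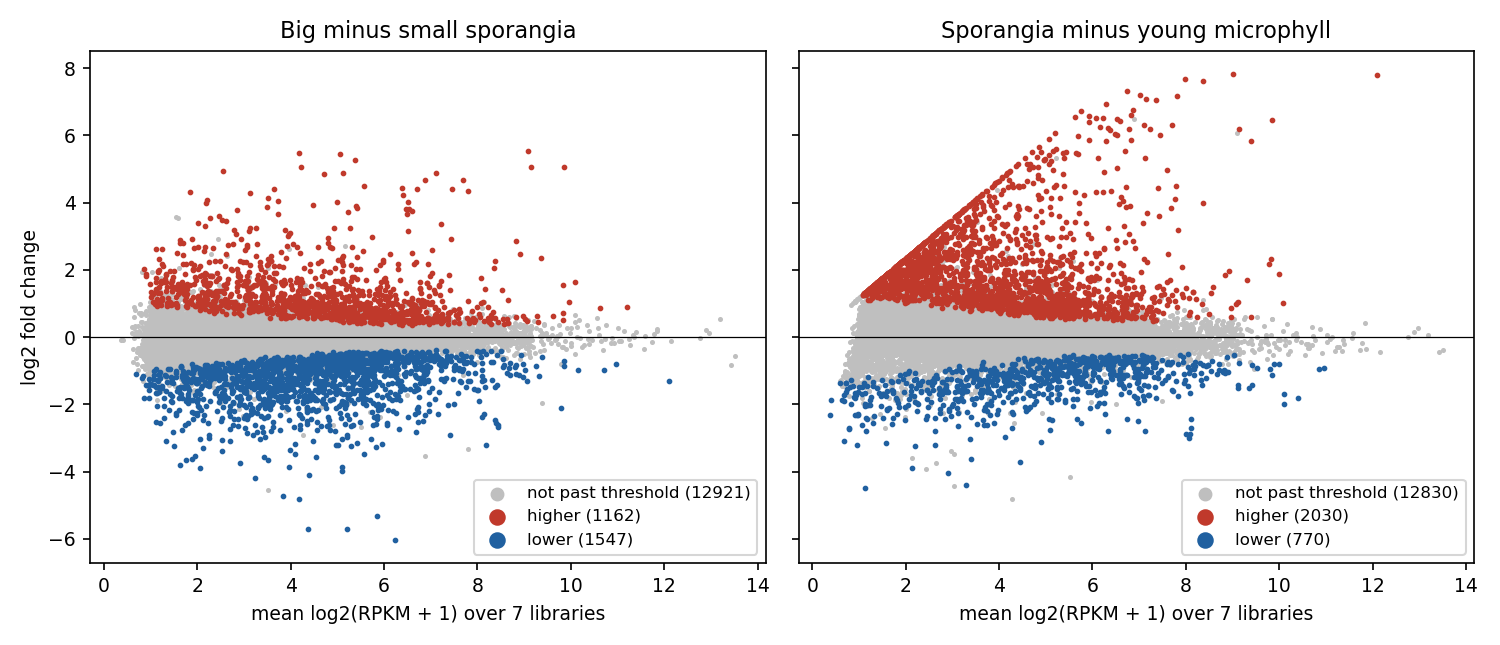
Log2 fold change against mean log2(RPKM + 1) over the 7 libraries for the 15630 genes tested, big minus small sporangia on the left and sporangia minus microphyll on the right, with each point a gene and colour marking genes past an adjusted p of 0.05 in limma. On the left 1162 genes were higher and 1547 lower, and on the right 2030 were higher and 770 lower, with an upper edge set by genes at 0 in the microphyll.

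Sporangia were compared with young microphyll to find transcripts that set the spore-bearing organ apart from the leaf that the design names as control. Of the 15630 genes tested, 2030 were higher and 770 were lower in sporangia. The 2030 higher genes held 12.5% ± 2.16 of reads in sporangia (SD, n = 6) and 3.23% in the microphyll. The 770 lower genes held 6.75% ± 0.60 of reads in sporangia (SD, n = 6) and 14.6% in the microphyll, where 283 of them reached 100 RPKM. Genes higher in sporangia were the less abundant, with a median of 12.2 RPKM over the group means against 42.5 RPKM for the lower genes.

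In the fit to the deposited values the changes toward sporangia were also the larger ones. Of the 2030 higher genes, 661 had at most 3 reads in the microphyll. The median log2 fold change was 1.61 among the higher and -1.23 among the lower genes, relative to a median of 0.11 over all genes as deposited. At least 4-fold separated 733 higher and 99 lower genes, and at least 16-fold 134 and 3. All 6 sporangium libraries lay at least 2-fold above the microphyll for 1557 genes, of which 1266 passed the test, and at least 2-fold below it for 283 genes, of which 239 passed. Detection was compared library by library at similar depth. Between 138 and 225 genes had 20 or more reads in a sporangium library and 0 in the microphyll. The reverse held for 8, 6 and 1 genes in small replicates 1 to 3 and for 4, 28 and 30 genes in big replicates 1 to 3. In all 6 sporangium libraries 745 genes were listed that had 0 reads in the microphyll, and 76 of them had 20 or more reads in each sporangium library. Absence from all 6 sporangium libraries is harder to meet than absence from 1 microphyll library, and 47 genes listed in the microphyll met it, none with more than 2 reads there.

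Among called genes whose sporangium libraries all lay on one side of the microphyll, genes 77903 and 425085 had the largest positive log2 fold changes with a pseudocount of 1 RPKM. Gene 77903 averaged 1214 ± 536 RPKM in sporangia (SD, n = 6) and had 14 reads, or 3.95 RPKM, in the microphyll. Its log2 fold change was 7.83 with an SE of 0.28 (limma, adjusted p = 7.11e-07). That SE rests on the spread of the sporangium libraries, as the microphyll has no replicate. With voom on the recovered reads the log2 fold change was 8.10 (limma with voom, adjusted p = 0.000431). Gene 425085 was among the most abundant transcripts, at 10564 ± 5102 RPKM in sporangia (SD, n = 6) and 41.8 RPKM from 68 reads in the microphyll, with a log2 fold change of 7.80 and an SE of 0.26 (limma, adjusted p = 5.2e-07). Both fell from the small to the big class, where gene 77903 stood at 1626 ± 449 RPKM against 802 ± 91 in the big class, and gene 425085 at 15056 ± 1928 RPKM against 6071 ± 907 (SD, n = 3 in each class), with log2 fold changes from small to big of -0.98 and -1.31 (limma, adjusted p = 0.0138 and 0.00253).

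Under the same rule and pseudocount, genes 139061 and 230161 had the largest negative log2 fold changes. Gene 139061 had 0 reads in every small library, 2, 1 and 1 reads in the big libraries, and 38 reads, or 30.4 RPKM, in the microphyll. The log2 fold change was -4.48 with an SE of 0.36 (limma, adjusted p = 8.45e-05), and as most of its sporangium values are at or near 0 the size depends on the pseudocount, from -6.55 with 0.1 RPKM to -2.69 with 5 RPKM. On these few reads gene 139061 was also called higher in big than in small sporangia, at a log2 fold change of 0.99 (limma, adjusted p = 0.0365). The counts between the size classes thus also hold a call on values near 0. Gene 230161 averaged 8.40 ± 7.56 RPKM in sporangia (SD, n = 6) and 133.7 RPKM from 350 reads in the microphyll, a log2 fold change of -4.40 with an SE of 1.13 (limma, adjusted p = 0.0282). It is 1 of 12 genes picked for at least 20 RPKM in the microphyll and a mean over big replicates 2 and 3 under 1/50 of that. It held 55 reads in big replicate 1, 2 in each of big replicates 2 and 3, and 18, 32 and 29 in small replicates 1 to 3. Without big replicate 1 its log2 fold change was -5.01. It missed the threshold at log2 fold changes of -4.83 with a pseudocount of 0.1 RPKM and -4.40 without the filter and without the variance trend (limma, adjusted p = 0.0523, 0.0645 and 0.0502).

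**Figure D3:**
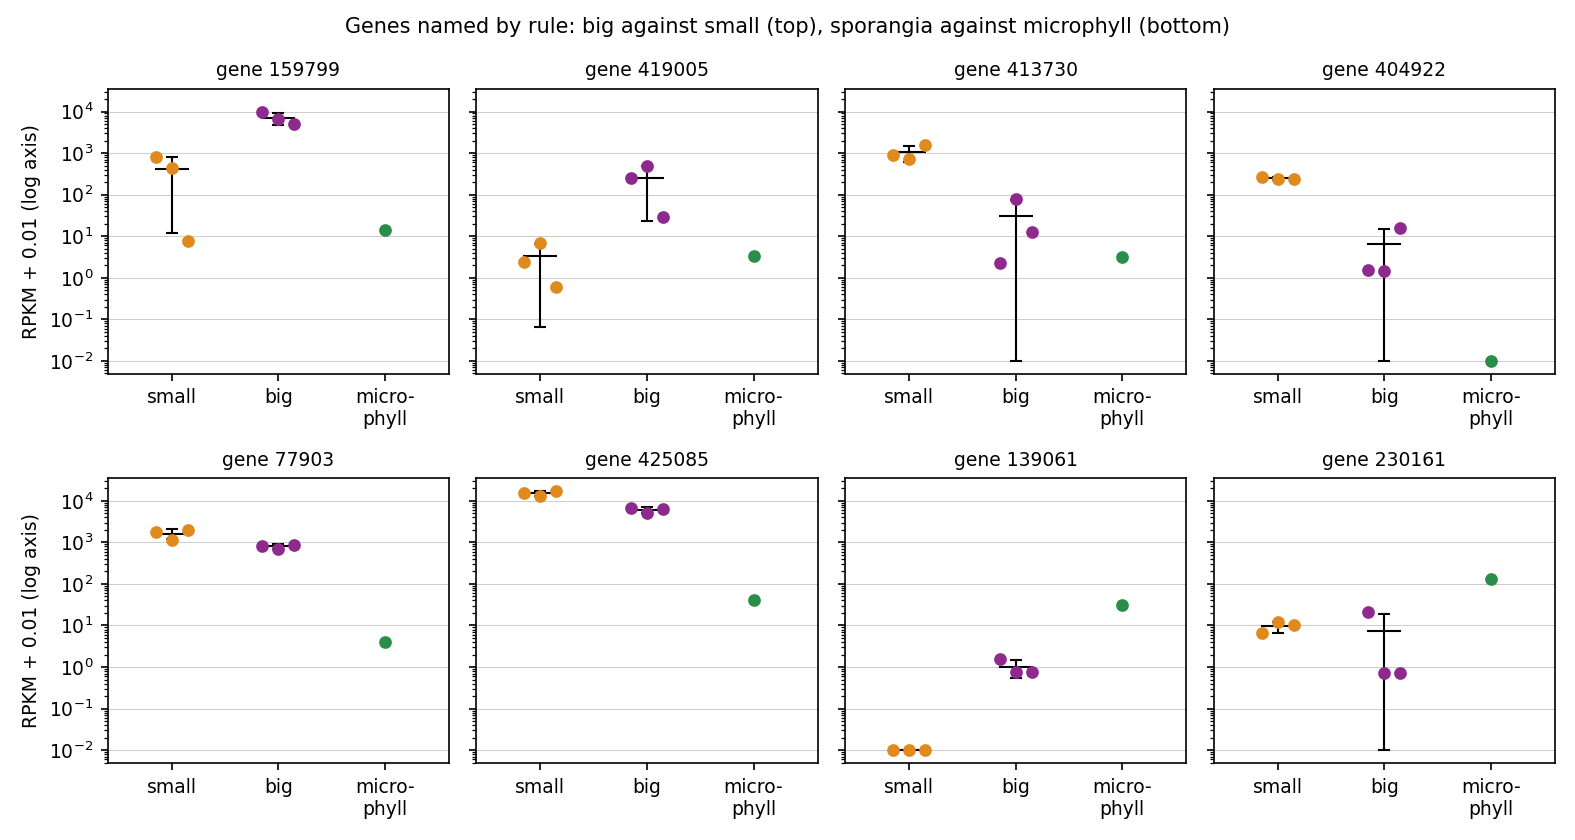
RPKM of the 8 named genes in each library on a log axis, with 0.01 RPKM added so that values of 0 can be drawn, points for single libraries, and black lines for the mean and SD of the 3 small and the 3 big libraries (a lower bar that would pass 0 stops at 0). Gene 159799 spreads from 7.83 to 821 RPKM within the small class, while genes 77903 and 425085 lie above the microphyll in all 6 sporangium libraries.

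The test was limma, which 2800 genes (17.9%) passed at an adjusted p below 0.05, and 5072 genes had an unadjusted p below that value. In simulated data the share of false calls in this comparison was above 0.05. All 6 sporangium libraries lay on one side of the microphyll for 2724 of the 2800 genes and for 50.9% of all genes tested, where chance gives 28.6%. The microphyll side has no replicate, and the balance of higher to lower genes depended on the processing. The share of calls that were higher was 72.5% as deposited, 61.8% with median ratio scaling, 60.1% after quantile normalization with 1203 genes higher, 57.7% with voom on the recovered reads with 1263 genes higher, and 48.2% with voom and trimmed mean scaling together, with 1106 genes higher and 1188 lower.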

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

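The limma calls and the scalings were planned, while the counts on opposite sides of the leaf, the other splits, voom, the library-by-library detection counts and the use of the scalings to weigh the surplus were chosen after the results were seen. Genes on which the size classes lay on opposite sides of the leaf were singled out, because every library of a class moved one way from the microphyll and every library of the other class moved the opposite way. Only genes that differed between big and small sporangia in limma at an adjusted p below 0.05 were counted. Of the 1162 genes higher in big sporangia, 182 had all 3 big libraries above and all 3 small libraries below the microphyll. Of the 1547 lower genes, 481 had all 3 small libraries above and all 3 big libraries below it. Called genes have a gap between the classes, so a single microphyll value falls inside it for part of them by chance. That chance share was not worked out. The distance of each class from the single microphyll library was not tested. With at least 2-fold asked on either side, 3 and 16 genes were left.

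The difference between big and small sporangia was set against other splits of the same 6 libraries into 3 and 3. The real split gave 2709 genes past the threshold in limma, and 1 of the 10 splits, the real one, gave as many. The highest count of the other 9 was 0, also with voom on the recovered reads, and they gave between 198 and 857 genes at an unadjusted p below 0.05. With 10 splits the share cannot fall below 0.1, which is too few for a share under 0.05. Each of the other 9 splits also puts libraries of both size classes in each group. The difference between the classes then adds to the spread within groups, so a count of 0 there is no chance level for the real split.

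Genes called higher in sporangia outnumbered those called lower against the microphyll, 2030 to 770. Scaling between the libraries alone did not remove this surplus, since 60.1% of calls were still higher under the scaling that lowered the share most. Voom alone, which weights genes by their reads, did not remove it either, with 57.7% of calls higher. Its weights rest on the spread of the sporangium libraries, so it cannot exclude error in the single microphyll library. Equal numbers of higher and lower calls are also not a known expectation here. The 786 genes called higher only without voom had a median of 5 microphyll reads, against 28 for those called higher either way. Trimmed mean scaling, which shifts all genes of a library alike, took the higher calls of voom from 1263 to 1106 and the lower calls from 925 to 1188. With voom and trimmed mean scaling together the share was 48.2%, so both acting together may account for the surplus in the number of calls. Both together do not account for clearly detected genes, since each sporangium library had at least 138 genes with 20 or more reads there and 0 in the microphyll, against at most 30 in reverse and at most 31 between any sporangium libraries. Whether that part belongs to the organ or to the single microphyll library stays open, since the leaf has no replicate.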

How the results depend on the processing

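Voom, voom with trimmed mean scaling and leaving out big replicate 1 and small replicate 1 together were chosen after seeing the data, and the other settings were planned. Of the counts of called genes under the alternatives, 106 stayed within 1.5 times the value reported and 11 did not. Those for big against small sporangia were 1482 genes, 600 higher and 882 lower, with a limit of 1 on the absolute log2 fold change, which keeps fewer genes by construction. Leaving out single libraries gave 1752 to 2494 genes, 680 to 1016 higher and 1072 to 1490 lower. The low end came without big replicate 2, and 737 genes were higher without big replicate 3 and 770 without small replicate 2, where a class has fewer libraries. For sporangia against microphyll 1203 genes were higher after quantile normalization, 1263 with voom, and 1106 with voom and trimmed mean scaling, which called 1188 lower. Leaving out single libraries gave 2328 to 2925 genes, 1734 to 2049 higher and 594 to 876 lower. Without big replicate 1 and small replicate 1 together the counts were 2482 and 2971. Voom shared 2548 of the 2709 calls between size classes and 1988 of the 2800 calls against the microphyll. The median log2 fold change of all genes against the microphyll was 0.11 as deposited, 0.00 with trimmed mean scaling, -0.01 with the median ratio and -0.07 after quantile normalization. No named gene changed direction. Leaving out libraries could not reverse these genes, since they were picked for sides that do not overlap. Their calls held in 148 results, among them the limit on the fold change, which repeats the reported value and adjusted p of each gene. Calls were lost in 8 results, and the cause was not tested. These were 5 for gene 159799 (limma, adjusted p from 0.00107 to 0.0736 over its alternatives) and 3 for gene 230161 (9.04e-05 to 0.0645). Summing near-identical copies and all gene list tests were not run, since the IDs were paired with neither sequences nor names. No paired analysis was possible because the title numbers 1 to 3 and 4 to 6 are not shared between the size classes. Depth limits the comparison with the microphyll, where 661 of the genes called higher had at most 3 reads.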

Other observations

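The limma calls were planned, while the overlaps, the positions, the dilution measure, the chi-square test of gene profiles and voom were chosen after the results were seen. Part of the genes called against the single microphyll library were also called between the size classes. Of the 2030 genes higher in sporangia, 451 were also higher in big and 306 lower in big sporangia, where independent lists of these sizes would share 151 and 201. Of the 770 genes lower in sporangia, 117 were higher and 143 lower in big sporangia, against 57.2 and 76.2 for independent lists. Across the 15630 genes tested the fold changes of the comparisons correlated at r = 0.18 with a covariance of 0.129. In 50 simulated sets of unchanged libraries the mean r was 0.00125 and the mean covariance 0.000138. Independent noise of equal size in the sporangium libraries cancels between these contrasts. The low simulated values were therefore fixed by the design and set no chance level for the r of 0.18. Both comparisons share an estimate of variance for each gene, so part of the excess over independent lists may come from that shared estimate. With voom on the recovered reads, 1263 genes were higher in sporangia, so the overlap counts also depend on the test.

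On genes higher in big sporangia, picked for each library from the others, positions were taken on the log2(RPKM + 1) scale. Small replicate 1 lay at 0.285 of the way from small to big and replicates 2 and 3 at 0.0083 and -0.0086. A group of 21 genes with a mean of at least 100 RPKM in big sporangia and under 1/50 of it in small replicate 3 took 6.17%, 4.07% and 3.03% of reads in big replicates 1 to 3, and 0.604% and 0.280% in small replicates 1 and 2, while the 0.0197% in replicate 3 was set by the choice of genes. RNA of big-type sporangia in the sample of small replicate 1 is a candidate explanation, since genes of 4 ranges of the replicate 3 level sat at similar positions. In RPKM, a scale on which the 0.285 above cannot be read, their medians were 0.122 to 0.146 of the way to the big mean. The ratio between the highest and lowest was 1.20. Replicate 2 sat lower and less evenly at 0.053, 0.035, 0.021 and 0.056, and replicate 3 set against replicate 2 gave -0.041 to 0.076. Dilution of transcripts higher in small sporangia, which such RNA would bring to the same degree, had a median of -0.034 against replicate 3 (95% bootstrap interval over genes -0.104 to 0.083) and 0.017 against replicate 2 (-0.037 to 0.077), short of that share, but the same measure gave 0.128 for replicate 2 against 3 and 0.212 for 3 against 2, so differences between single libraries are too large to decide it. A later stage of small replicate 1 within its class was not tested and stays open as well.

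A group of 12 genes was picked for 20 RPKM or more in the microphyll and a mean over big replicates 2 and 3 under 1/50 of that. In these genes big replicate 1 held a median of 0.228 of the microphyll level and the small libraries 0.0623, 0.193 and 0.111. The choice of genes set the low values in big replicates 2 and 3, and so part of their gap to replicate 1. No group was picked in the same way around replicate 2 or 3. Microphyll-like RNA in big replicate 1 at a share of 0.228 would put genes of every range at 1 position between big replicates 2 and 3 and the microphyll. The medians, in RPKM, were 0.226 for the 12 genes (95% bootstrap interval over genes 0.153 to 0.263) and 0.188 for genes at 0.02 to 0.1 of the microphyll level in big replicates 2 and 3 (0.136 to 0.255). They were 0.0999 at 0.1 to 0.25 (0.0759 to 0.139) and 0.0934 at 0.25 to 0.5 (0.0582 to 0.110). In these upper ranges big replicate 2, placed between the mean of the other big libraries and the microphyll, sat at -0.054 and -0.052. Big replicate 3, placed in the same way, sat at -0.014 and 0.043. The 12 genes set that share, so their own position is no check on it. For big replicate 1 the range at 0.02 to 0.1 goes with that share and the upper ranges go against it. A smaller share stays possible. A single foreign source with a fixed profile, such as another organism, could not be settled. The reads of the 12 genes over the 5 libraries that hold them gave a chi-square per degree of freedom of 28.1. It was 8.58 without the most deviant gene, and 15.2 with all 12 genes over the sporangium libraries among these. Pairs of libraries of a class reached 16.1, but over many more genes of all abundances, so that value is no like measure for 12 genes. A difference of stage between the big libraries was not tested.

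The number in the sample titles runs from 1 to 6 over the sporangium libraries, and the labels do not say that it is an order. Each library was judged on the log2(RPKM + 1) scale, on genes picked from the others. On genes higher in big sporangia the small libraries 1 to 3 lay at 0.285, 0.0083 and -0.0086 of the way from small to big. The big libraries 4 to 6 lay at 0.995, 0.969 and 0.838. The position rose with the title number in 0 of the 4 neighbouring pairs within a class. On genes higher in small sporangia the positions were -0.039, 0.040 and 0.127 for small and 0.829, 1.095 and 0.887 for big libraries, which rose in 3 of the 4 pairs, and over both kinds of gene 2 of the 4 rose. With 1 library for each number no spread can be set against this, and an order of stages along the titles cannot be told apart from differences between libraries.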
